A study of Mus musculus with 4 samples.

How the data were processed

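Total RNA from whole mouse brain was measured on 4 single-colour (Cy3) Agilent expression arrays, 1 for each combination of genotype and injection. The genotypes, per the labels, were wild-type and Nav1.8Cre-ROSA26DTA, and the injections were phosphate-buffered saline (PBS) and lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria). In Nav1.8Cre-ROSA26DTA mice, Cre recombinase driven from the gene of the sodium channel Nav1.8 (Scn10a) switches on diphtheria toxin A, which ablates the Nav1.8 lineage of sensory neurons, chiefly nociceptors. LPS was given into the peritoneum at 20 mg/kg and brains were taken 12 hours later, per the labels' protocols. The labels do not say whether an array holds RNA of 1 mouse or of a pool, so the group and the individual animal cannot be told apart.

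RNA was extracted with TRIzol and labelled with Agilent's low-input kit, per the labels' protocols. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1, whereas the file headers name version 12.0.3.1, a single-colour gene expression protocol and the mouse build mm9 for the design grid. The deposited spot intensity used here, the processed signal, is the spot's brightness after background subtraction and detrending within the array, per the file headers, with no scaling between arrays. The flags for spots well above background, saturated or non-uniform are 0 or 1 values of the same software, per the file headers. The deposited value table, an intensity on a linear scale, was compared with the scanner values probe by probe. Each of its columns equalled the processed signal of the same array times 1 factor (1.82, 2.09, 1.83 and 1.57 for wild-type PBS, Nav1.8Cre-ROSA26DTA PBS, wild-type LPS and Nav1.8Cre-ROSA26DTA LPS), within 0.1% for at least 59304 of 59305 spots. The column medians were 97.2, 91.4, 103 and 102 in the same order, and how the factors were set is not given in the sources used here.

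All 4 arrays lay on 1 slide read in 1 scan, so no slide or scan batch exists within the data. The position on the slide was tied to the groups, with PBS arrays in one row, LPS arrays in the other, and the genotypes in different columns, so position and group cannot be told apart. Each array held 59305 spots that were not controls, for 56605 probes. Between 66.5% and 69.5% of spots were well above background, 0 were saturated, and 81 to 96 spots per array carried an outlier mark and were left out. Over 299 probes printed as 10 spots, the spot-to-spot SD was 0.0418 to 0.0455 on the log2 scale, which is technical error within an array. The number of arrays, 1 per group, limits the precision of every value.

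Values were log2 of the processed signal minus the array's 75th percentile, which was 612, 514, 634 and 726 in the order given above. Spots of a probe were averaged. Probes were named through their RefSeq accessions with a gene table of GRCm38.p6, used for names and gene order only. Of 56605 probes, 33762 (59.6%) had 1 symbol and 22843 had none. A gene was represented by the probe well above background on the most arrays, then by the highest mean, giving 23457 genes. Of these, 16240 were well above background on all 4 arrays, 17128 on at least 2, and 5515 on none. Over the 5990 to 6143 genes with several probes measured in a comparison, the median SD between a gene's probes was 0.10 to 0.15 on the log2 scale. Probes for haemoglobin genes share sequence with paralogs, so which haemoglobin gene a value belongs to is uncertain.

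LPS against PBS, averaged over both genotypes, and Nav1.8Cre-ROSA26DTA against wild-type, averaged over both injections, were estimated in 1 linear model with terms for genotype and agent, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over the 17128 genes. Each averaged effect sets 2 arrays against 2, and the model leaves 1 residual degree of freedom, the difference of the LPS responses, which limma pools across genes. A true difference of response between genotypes therefore counts as error. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, and errors given as ± are limma's standard errors. The labels give no separate animals within a group, so p-values do not measure the spread between animals. Each ± and p-value combines the gene's own residual, with 1 degree of freedom, with that of genes of like intensity, with 7.99. An error given as ± therefore reflects other genes more than the gene's own 2 responses. The 4 comparisons of 2 arrays and the difference of the LPS responses have no replicate error and no test. For these, genes measured on all arrays of the comparison and at least 2-fold apart were counted. Where a gene was not well above background in 1 group, the bright mean was set against the higher of the array's lowest signal well above background and the gene's own signal, and reported as at least N-fold. The adjusted p of such a gene comes from the model on its measured signals, dim ones included, so it does not test the bound.

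A set of 38 gene lists, covering inflammatory pathways, brain cell types, blood and immune cells, brain regions, stress responses, nociceptors, sex-linked genes and the transgene loci, were fixed together with the tests and the alternatives before the data were examined. For averaged effects, lists with at least 5 tested members were tested with camera (limma) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of an effect. Camera ranks a list against all other genes, so its direction can differ from the sign of the list's median. Some lists share members, such as 6 of 23 activated endothelium and 8 of 37 cytokine and NF-kB genes, so results of such lists are not separate. For single comparisons a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and was said to stand apart below the 1st or above the 99th percentile, as a description of these arrays. Named genes followed a fixed rule. For each averaged effect it took the 15 largest increases and 10 largest decreases that passed and went the same way in both pairs. For each single comparison it took the 10 largest differences of at least 2-fold and the 3 largest bounds per direction, and from each list up to 4 members with the largest difference. Scn10a, Reg3g, Extl3 and the kynurenine list were always kept, and probes named only as clones or gene models were counted.

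The model was tested on simulated data built on the 17128 genes of the LPS comparison, with 200 changed genes in each of 20 simulations. It recovered 81.6% of genes changed 2-fold and 96.7% of those changed 4-fold, but a median of 14.4% and at most 36.8% of its calls were false, and it made a median of 1 and at most 85 calls for genotype where no difference was simulated. Without the intensity trend, 0% of 2-fold and 83.2% of 4-fold changes were recovered, with a median of 5.07% false calls. The list percentile placed 40 of 40 simulated lists shifted by 1 (log2) above the 99th percentile and 0 unshifted lists apart. Smaller shifts, like many list medians reported here, were not simulated. Both simulations drew values independently between genes. Neither therefore gives the rate of false calls for genes that vary together, as members of a list may. Refitted to the simulated arrays, the model with the trend had a median of 12.8 prior degrees of freedom, against 7.99 for the real ones, so it pooled more strongly. No difference of LPS response between genotypes was simulated either, so these rates of false calls need not hold for the real arrays. Alternatives covered background correction (normexp with an offset of 50, on median spot signals because mean signals are not among the columns used here), quantile, cyclic loess and median scaling, the filter and floor for dim probes, the mean of a gene's probes, the deposited value table, a fit without trend or without the genotype term, each array left out, camera with an estimated correlation, fry, and a threshold of 1.5-fold. Leaving out each array for the genotype effect, in a fit with genotype as the only term, was added after the data were examined. Numerical work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Scn10a expression in sensory ganglia, the site of ablation, was not analysed here. Single results for some genes are not reported here.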

Results

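Gene expression was measured in whole brain of wild-type mice and of Nav1.8Cre-ROSA26DTA mice, whose Nav1.8-lineage sensory neurons are ablated, after an injection of PBS or of LPS at 20 mg/kg with sampling at 12 hours. The 4 groups held 1 array each, so no difference within a pair of arrays has a replicate check, and the number of arrays limits the precision throughout. A dose of LPS this high is widely used as a model of septic inflammation. The design asks what LPS did to brain expression and whether the loss of nociceptors altered the brain at rest or its response. Averaged effects set 2 arrays against 2 and carry limma's standard error and adjusted p. Of 23457 genes, 17128 entered that model.

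Scn10a, the gene of Nav1.8 whose promoter drives the ablation, differed between genotypes by −0.33 (log2) with PBS and by 0.47 with LPS, averaging 0.07 with an adjusted p of 0.943. These values check nothing about the ablation, since sensory ganglia were not measured. Within the brain Scn10a rose with LPS by 2.69 ± 0.19 (adjusted p = 2.2e-05), by 2.28 in wild-type and 3.09 in Nav1.8Cre-ROSA26DTA. The list of 9 strain and transgene-locus genes had a median of 0.30 for LPS with 2 genes up (4 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.651 with an estimated correlation), or 0.14 without wild-type LPS, and of 0.09 for genotype with 0 genes passing over all genes (adjusted p = 0.587). Its genotype median was −0.22 with PBS, where it stood apart from random lists as lower, and 0.0765 with LPS. The PBS median turned positive with normexp. In that list Gt(ROSA)26Sor, the locus that carries the toxin allele, was lower in Nav1.8Cre-ROSA26DTA by −0.51 with PBS and −0.52 with LPS, with an adjusted p of 0.065. The 11 nociceptor and sensory neuron genes had medians of −0.12 for LPS (adjusted p = 0.656) and 0.07 for genotype (adjusted p = 0.838). Within pairs of arrays their medians were −0.25 for LPS in wild-type and −0.20 for genotype with PBS, both apart as lower. Both turned positive without the filter on dim probes, and the PBS one also with normexp. The medians were −0.0170 for LPS in Nav1.8Cre-ROSA26DTA and 0.16 for genotype with LPS. The 8 sex-linked genes had medians of −0.04 (adjusted p = 0.737) and −0.03 (adjusted p = 0.356). Y-linked genes such as Ddx3y and Uty were well above background on all 4 arrays, while Xist was on none.

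With LPS, 26 of 28 type I interferon-stimulated genes and 27 of 33 cytokine and NF-kB target genes rose, and 9 of 18 homeostatic microglia genes fell. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose by 8.30 ± 0.23 on the log2 scale (adjusted p = 8.9e-08). The chemokine genes Ccl5 and Cxcl10 rose by 7.12 ± 0.18 and 6.97 ± 0.17. Several of the strongest genes were not well above background on either PBS array and have bounds only. Among these, the acute-phase gene Saa3 was at least 3113-fold higher, the metalloproteinase gene Mmp3 at least 86.0-fold and the neutrophil chemoattractant Cxcl1 at least 54.8-fold. In total 963 genes rose and 777 fell in limma's test, 546 and 96 of them by at least 2-fold. Scaling altered the balance, to 939 up and 433 down with cyclic loess, 1043 and 433 with the deposited value table, and 963 and 1290 with scaling to the median. Without the intensity trend 382 rose and 49 fell. With an array left out the calls were 415 up and 187 down (wild-type PBS), 514 and 70 (Nav1.8Cre-ROSA26DTA PBS), 457 and 166 (wild-type LPS) or 370 and 91 (Nav1.8Cre-ROSA26DTA LPS).

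In each list of inflammatory signalling genes most tested members rose. Of 33 cytokine and NF-kB target genes, 27 rose, 0 fell and 6 did not pass, with 28 up when adjusted over the list alone and a median of 1.41. Among them Ch25h, a cholesterol hydroxylase gene, rose by 4.85 ± 0.32 and the NF-kB coactivator Bcl3 by 3.60 ± 0.16, while Csf3, the gene of granulocyte colony-stimulating factor, was at least 12.3-fold and the interleukin-1 receptor antagonist Il1rn at least 2.84-fold higher. Of 28 type I interferon-stimulated genes 26 rose and 0 fell (28 and 0 adjusted over the list alone; median 2.35), among them the transcription factor gene Irf7 (4.14 ± 0.22), Oasl1 (4.02 ± 0.22) and the nucleic acid sensor Zbp1 (3.82 ± 0.20). Of 32 interferon-gamma-inducible GTPase and antigen presentation genes 24 rose and 1 fell (24 and 2 adjusted over the list alone; median 1.91), including the GTPase genes Gbp2 (5.18 ± 0.15), Tgtp2 (4.80 ± 0.12) and Gbp4 (4.39 ± 0.18). Of 17 chemokine genes 10 rose and 2 fell, the same counts as adjusted over the list alone, with a median of 1.54, or 1.33 with dim signals at the floor. Complement genes rose in 12 of 16 cases (13 adjusted over the list alone; median 1.21), with Cfb at least 51.6-fold higher and C1ra and Serping1 up by 1.98 ± 0.15 and 1.84 ± 0.16. Camera's adjusted p was 2.5e-30 for cytokines, 2.4e-38 for type I and 2.4e-32 for interferon-gamma genes and 8.9e-15 for complement, but each had adjusted p = 0.651 with an estimated correlation. For chemokines it was 3.6e-08, and adjusted p = 0.709 with an estimated correlation. That setting rests on 1 residual degree of freedom, and the lowest adjusted p it gave any list of either effect was 0.651, so it says little about any single list. The preset correlation is assumed in the same fit rather than measured, so the lower adjusted p values hold only under it. With an array left out, the calls of Serping1 (adjusted p = 0.0977 without Nav1.8Cre-ROSA26DTA LPS) and Il1rn ended, the latter with 0.0581 to 0.127 without any array but wild-type LPS.

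Glial genes changed in both directions. Of 18 homeostatic microglia genes 9 fell and 1 rose (12 and 1 adjusted over the list alone; median −0.52), led by Gpr34 (−3.78 ± 0.24), the purinergic receptor gene P2ry12 (−2.73 ± 0.15) and Slc2a5 (−2.05 ± 0.16). Camera gave an adjusted p of 4.5e-07, and adjusted p = 0.709 with an estimated correlation. Of 24 activated microglia and macrophage genes 12 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.46), including the Fc receptor Fcgr4 (4.97 ± 0.22) and Spp1, or osteopontin (2.77 ± 0.12). Of 25 reactive astrocyte genes 19 rose and 0 fell (21 and 0 adjusted over the list alone; median 1.89), with Serpina3n, a serine protease inhibitor, up by 5.03 ± 0.19. Their adjusted p values were 9.3e-06 and 3.9e-25, each with adjusted p = 0.651 with an estimated correlation. The 16 homeostatic astrocyte genes had a median of −0.22, with 5 down and 1 up (8 and 1 adjusted over the list alone), among them the potassium channel Kcnj10 (−0.58 ± 0.09; list adjusted p = 0.018, adjusted p = 0.800 with an estimated correlation). Oligodendrocyte precursor genes fell in 6 of 11 cases, the same count as adjusted over the list alone (median −0.38), including Gpr17 (−1.27 ± 0.13) and the proteoglycan NG2 gene Cspg4 (−0.84 ± 0.13; list adjusted p = 7.7e-05, adjusted p = 0.651 with an estimated correlation). Of 19 oligodendrocyte genes 3 fell and 1 rose (11 and 1 adjusted over the list alone; median −0.33), such as Opalin (−1.03 ± 0.23) and Aspa (−0.93 ± 0.12), with an adjusted p of 0.001 and adjusted p = 0.800 with an estimated correlation. That list's direction turned without the wild-type LPS array (median 0.0561, adjusted p = 0.419), where the precursor median was −0.13, and both medians were −0.63 without Nav1.8Cre-ROSA26DTA LPS. Without that last array the medians were −0.33 for homeostatic and 0.26 for activated microglia. Without the Nav1.8Cre-ROSA26DTA PBS array the calls of the homeostatic astrocyte (median −0.14, adjusted p = 0.258), oligodendrocyte (−0.14, 0.213) and precursor lists (−0.20, 0.0759) ended, as did those of Kcnj10, Gpr17, Cspg4, Opalin and Aspa (0.0707 to 0.620). Calls also ended without wild-type PBS for Gpr17 (0.118), Opalin (0.339) and Aspa (0.0572). Without wild-type LPS those of Gpr17 (−0.78, adjusted p = 0.0787), Cspg4 (0.0807), Opalin (−0.23, adjusted p = 0.758) and Aspa (0.0899) ended, and without Nav1.8Cre-ROSA26DTA LPS those of Kcnj10 (0.0819) and Cspg4 (0.0921), while Opalin then stood at −1.84.

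Vascular, ventricular and white-cell lists also held genes that changed. Of 21 activated endothelium genes 11 rose and 0 fell, also when adjusted over the list alone (median 0.69), including the adhesion molecule gene Icam1 (2.88 ± 0.13) and Lrg1 (2.65 ± 0.11). Icam1 is also a member of the cytokine and NF-kB list. Of 23 neutrophil and monocyte genes 13 rose (13 up and 1 down adjusted over the list alone; median 2.04, or 1.72 with dim signals at the floor), including the decoy receptor gene Il1r2 (4.66 ± 0.16), and Clec4d, a C-type lectin gene, was at least 9.24-fold higher. The adjusted p values were 6.2e-12 and 6e-09, each with adjusted p = 0.651 with an estimated correlation. Of 17 choroid plexus genes 4 rose (5 adjusted over the list alone; median 0.34), among them the water channel Aqp1 (4.15 ± 0.22) and the LPS-binding protein gene Lbp (3.05 ± 0.26; list adjusted p = 0.0019, adjusted p = 0.709 with an estimated correlation). Lbp belongs to the cytokine and NF-kB list too. Of 11 ependyma and cilia genes 6 rose, also when adjusted over the list alone (median 0.64), such as Ccdc153 (1.54 ± 0.35; list adjusted p = 0.0016, adjusted p = 0.651 with an estimated correlation). The 25 brain endothelium and barrier genes went both ways, 4 up and 10 down (5 and 12 adjusted over the list alone; median −0.33; adjusted p = 0.0697). The amino acid transporter Slc38a5 fell by 2.40 ± 0.17 and Itm2a by 2.13 ± 0.12, whereas Ly6a rose by 2.46 ± 0.09. Pericyte, fibroblast and smooth muscle genes (17; median −0.09; 2 up and 3 down; adjusted p = 0.883), lymphocyte genes (12; median −0.11; 2 up and 0 down; adjusted p = 0.795) and erythroid and blood genes, a list of red cell and platelet genes (13; median −0.08; 0 passing; adjusted p = 0.462), were not called. Single PBS arrays decided the erythroid and fibroblast lists: without the Nav1.8Cre-ROSA26DTA one, erythroid and blood (adjusted p = 0.00161) and fibroblast lists (0.0149) were called higher, and without the wild-type one they were called lower (2.8e-06 and 0.0113). The choroid plexus call ended and its median turned to −0.0246 without wild-type PBS (0.106), against 0.59 without Nav1.8Cre-ROSA26DTA PBS. The neutrophil and monocyte median was 0.85 without wild-type PBS, the ependyma call ended without wild-type PBS (0.0800) or Nav1.8Cre-ROSA26DTA LPS (median 0.42, adjusted p = 0.119), and barrier genes were called lower without wild-type PBS (0.0486) or wild-type LPS (0.0465). Ccdc153 rested on the PBS arrays, at 0.32 without the wild-type one (adjusted p = 0.705) and 2.76 without the Nav1.8Cre-ROSA26DTA one (0.0331), and its call also ended without wild-type LPS (0.313) or Nav1.8Cre-ROSA26DTA LPS (0.761).

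LPS also raised most genes of the glucocorticoid-responsive list. Of its 20 genes 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.89), led by Map3k6 (2.46 ± 0.10), the cell-cycle inhibitor Cdkn1a (2.22 ± 0.10) and the steroid receptor co-chaperone Fkbp5 (1.71 ± 0.09). Camera gave an adjusted p of 2.2e-19, and adjusted p = 0.651 with an estimated correlation. Among 22 immediate early genes (median −0.05, adjusted p = 0.189) 7 rose and 1 fell (9 and 4 adjusted over the list alone). The synaptic gene Arc was up by 1.15 ± 0.09 and the neurotrophin gene Bdnf down (−1.09 ± 0.13). With an array left out the list's median ran from −0.17 (without wild-type LPS) to 0.17 (without wild-type PBS). In the kynurenine pathway of tryptophan breakdown (12 genes; median 0.14; adjusted p = 0.184) the first enzyme Ido1 rose by 1.07 ± 0.20 (adjusted p = 0.0093, or 0.0544 without the intensity trend), Kyat3 rose by 0.85 ± 0.12, and the tryptophan carrier Slc7a5 fell by 0.39 ± 0.10. The other members did not pass, Ido2 at 0.59 ± 0.17 and Kmo at 0.54 ± 0.35. The list's median was 0.10 in each genotype. Averaged over genotypes, it was 0.07 without wild-type PBS or Nav1.8Cre-ROSA26DTA LPS, and 0.21 without wild-type LPS. In the prostaglandin and fever list (15 genes; median −0.11; adjusted p = 0.656) the cyclooxygenase gene Ptgs2 rose by 1.41 ± 0.13 and Hpgd, which degrades prostaglandins, fell by 0.97 ± 0.17. Single members rose in lists that were not called, such as Hspb1 (2.51 ± 0.09) among 15 heat shock genes (median 0.02; adjusted p = 0.144), Mt2 (1.04 ± 0.14) among 16 metallothionein and oxidative stress genes (0.05; 0.0786), Adm (0.89 ± 0.15) among 16 hypoxia genes (0.06; 0.429) and Per3 (0.50 ± 0.12) among 17 clock genes (0.02; 0.297). Lists of neurons and brain regions were not called: pan-neuronal genes had a median of −0.09 (adjusted p = 0.111), cell cycle genes 0.19 (0.156), pituitary genes −0.01 (0.924), hypothalamic peptides −0.11 (0.656), striatum 0.03 (0.495), cerebellum and hindbrain −0.22 (0.501), and olfactory bulb, cortex and hippocampus 0.00 (0.733). The cell cycle median turned to −0.14 without wild-type PBS, and the pan-neuronal one was −0.03 without Nav1.8Cre-ROSA26DTA LPS. Histidine decarboxylase, Hdc, rose by 1.59 ± 0.18 within the hypothalamic list. Reg3g, an antimicrobial lectin gene, was not well above background on either PBS array and was at least 3.70-fold higher with LPS. Its adjusted p of 0.001 rests on the measured PBS signals, which lay below that background, and does not test the bound. Extl3, the gene of its proposed receptor, differed by −0.01 ± 0.10 (adjusted p = 0.974), and the REG3 list had too few members to test. With arrays left out in turn, the calls of Ido1, Hpgd, Per3, Adm and Slc7a5 ended each time (adjusted p = 0.0599 to 0.863), with Slc7a5 at −0.66 without wild-type LPS and −0.13 without Nav1.8Cre-ROSA26DTA LPS. Those of Kyat3 and Bdnf ended without wild-type PBS (0.0560 and 0.0924) or Nav1.8Cre-ROSA26DTA LPS (0.0700 and 0.0685), that of Kyat3 also without wild-type LPS (0.0674) and that of Bdnf without Nav1.8Cre-ROSA26DTA PBS (0.0534). The call of Hdc ended without Nav1.8Cre-ROSA26DTA LPS (0.0561). Without the Nav1.8Cre-ROSA26DTA PBS array the pan-neuronal list was called lower (0.0204) and cell cycle (0.0149) and metallothionein lists (0.0486) higher, the last also without Nav1.8Cre-ROSA26DTA LPS (0.0417).

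Within each genotype no test was possible. The wild-type response to LPS comprised 562 genes at least 2-fold higher and 102 lower of 16490 measured. In Nav1.8Cre-ROSA26DTA it comprised 513 and 235 of 16526. Lcn2 was 8.91 higher in wild-type and 7.69 in Nav1.8Cre-ROSA26DTA, Ccl5 7.51 and 6.72, Cxcl10 7.15 and 6.80, and the scavenger receptor gene Marco 3.86 and 7.08. Saa3, with a bound only, was at least 2129-fold higher in wild-type and at least 4552-fold in Nav1.8Cre-ROSA26DTA. Gpr34 (−3.30 and −4.27) and P2ry12 (−2.57 and −2.89) were among the lowest of both. Of genes measured on all 4 arrays, 373 were at least 2-fold higher in both responses, against 16.2 for independent lists, and 43 were lower in both, against 1.32. The responses correlated across genes with a Pearson coefficient of 0.73 and a Spearman coefficient of 0.49, genes not being independent replicates. In wild-type 16 lists stood apart as higher and 5 as lower of 36 ranked, and in Nav1.8Cre-ROSA26DTA 13 and 5 of 37. Scaling to the median moved the median of all genes in the Nav1.8Cre-ROSA26DTA response to −0.11, against −0.04 as reported. Without the filter on dim probes 1311 genes were higher and 655 lower in wild-type, and 1310 and 806 in Nav1.8Cre-ROSA26DTA.

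**Figure D1:**
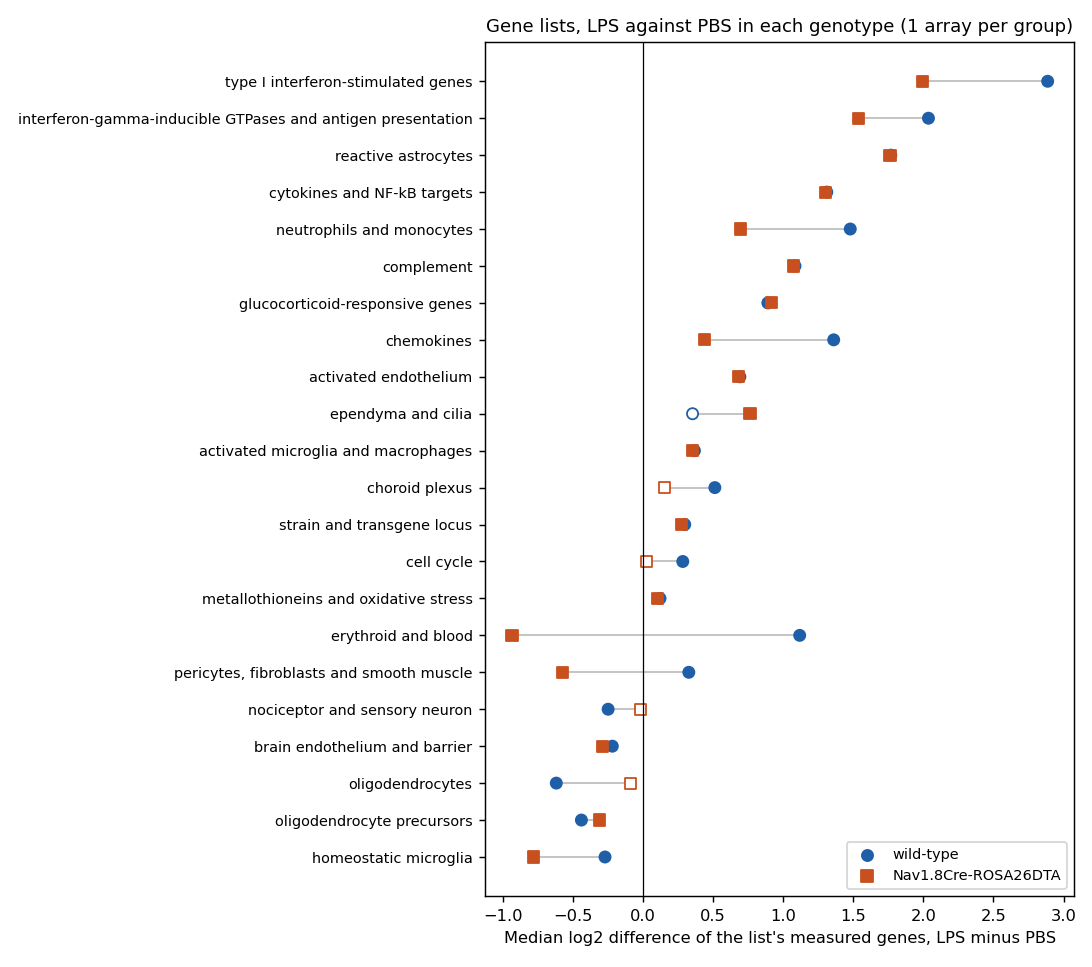
Median log2 difference of each gene list, LPS minus PBS, in wild-type (circles) and Nav1.8Cre-ROSA26DTA (squares), 1 array per group, for lists that stood apart from random lists in either genotype, with filled symbols marking where they did. Type I interferon-stimulated genes lie at 2.89 in wild-type and 1.99 in Nav1.8Cre-ROSA26DTA, and erythroid and blood genes lie on opposite sides of 0.

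In the untested difference of the responses, lists of blood, connective-tissue, neutrophil and interferon genes stood apart as lower in Nav1.8Cre-ROSA26DTA. Type I interferon-stimulated genes had a median of 2.89 in wild-type and 1.99 in Nav1.8Cre-ROSA26DTA, and the median of the member-by-member differences was −0.75, with 8 of 27 at least 2-fold smaller and 0 larger, such as Ifi27l2a (−1.95), Oas2 (−1.52) and Rsad2 (−1.46). Interferon-gamma-inducible genes had a median difference of −0.32, including the class II antigen presentation genes H2-Aa (−2.02) and H2-Eb1 (−1.96). Chemokines had a median difference of −0.46, with Ccl2 at −2.69 and Ccl12 at −2.64, and neutrophil genes −0.34, with the calprotectin genes S100a9 at −3.76 and S100a8 at −3.63. Erythroid and blood genes had a median of 1.12 in wild-type and −0.94 in Nav1.8Cre-ROSA26DTA, a median difference of −2.13 over 10 genes, and the pericyte, fibroblast and smooth muscle list went from 0.33 to −0.57. The homeostatic microglia list was −0.27 in wild-type and −0.78 in Nav1.8Cre-ROSA26DTA, and the microglial receptor gene Trem2 was −2.12 in the latter. Oligodendrocyte genes went the other way, with a median of −0.62 in wild-type and −0.09 in Nav1.8Cre-ROSA26DTA and a median difference of 0.44. Choroid plexus (−0.69), brain endothelium (−0.27), activated microglia (−0.32) and reactive astrocyte (−0.23) lists also stood apart as lower. In all, 157 genes had a response at least 2-fold larger in Nav1.8Cre-ROSA26DTA and 249 a smaller one, of 16240. That balance did not extend to measured probes with no gene name, where 546 of 11031 had a larger response and 118 a smaller one. Of the lists, 1 stood apart as higher and 11 as lower of 36. Between genotypes the erythroid and blood, connective-tissue, neutrophil and type I interferon lists had medians of 1.82, 0.80, 0.40 and 0.49 with PBS against 0.61, −0.04, 0.27 and −0.18 with LPS. On the Nav1.8Cre-ROSA26DTA PBS array 10 of 10 erythroid and blood and 12 of 17 connective-tissue genes were at their highest. No test of the difference is possible with 1 array per group, and normexp background correction left 45 and 71 genes.

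**Figure D2:**
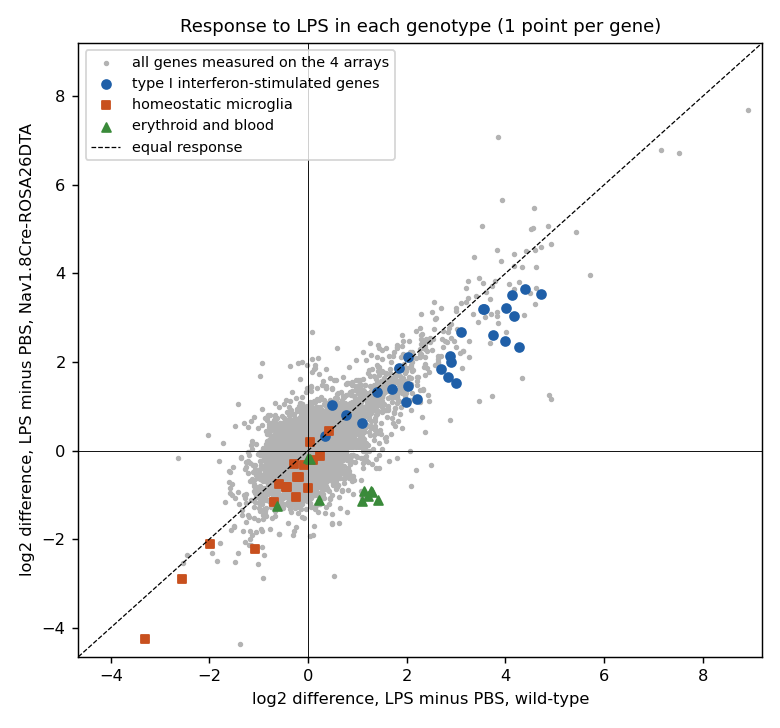
Response to LPS of each gene (log2, LPS minus PBS) in Nav1.8Cre-ROSA26DTA on the vertical axis against wild-type on the horizontal axis, 1 point per gene measured on the 4 arrays, with type I interferon-stimulated genes as circles, homeostatic microglia genes as squares, erythroid and blood genes as triangles and a dashed line of equal response. Most genes higher in one genotype were higher in the other, 373 of them by at least 2-fold in both.

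Averaged over both injections, brains of Nav1.8Cre-ROSA26DTA mice had higher levels of a small set of genes than wild-type brains, with myelin genes among them. The synaptic vesicle gene Sv2c was higher by 2.80 ± 0.26 (adjusted p = 0.0043), the glycogen-binding gene Stbd1 by 2.52 ± 0.15 (adjusted p = 0.00026) and the corepressor gene Tle1 by 1.81 ± 0.11 (adjusted p = 0.00026). Haptoglobin, Hp, was up by 2.32 ± 0.23 and the cerebellin gene Cbln1 by 1.60 ± 0.14, while the haemoglobin gene Hbb-b2 was up by 2.74 ± 0.36, with probes that share sequence with its paralogs. Relative to wild-type, the haem oxygenase gene Hmox1 fell by 1.28 ± 0.20 (adjusted p = 0.046). In limma's test 52 genes were higher and 18 lower, 28 and 2 of them by at least 2-fold. Simulations with no genotype difference gave a median of 1 and at most 85 calls, a range that holds the number called here. Those simulations pooled across genes more strongly than the real fit and held no difference of LPS response, so their counts need not carry over. Without the intensity trend limma called 0 genes (lowest adjusted p = 0.145), with 1035 higher and 441 lower at an unadjusted p under 0.05. With any array left out, 1 genotype keeps 1 array and LPS counts as error, and those fits supported no call. Other settings gave from 15 higher and 4 lower (cyclic loess) to 654 and 304 (no filter on dim probes), and genotype cannot be told apart from the individual animals. The calls of Hbb-b2 and Hmox1 ended with cyclic loess, the mean of a gene's probes or the deposited value table.

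Among the lists, oligodendrocyte genes had the lowest adjusted p in camera for genotype. Of 19 such genes 4 rose and 0 fell over all genes, but 17 passed when adjusted over the list alone, with a median of 0.67. The myelin gene Mobp was higher by 1.31 ± 0.15 (0.96 with PBS, 1.67 with LPS) and Enpp6, a marker of newly forming oligodendrocytes, by 1.32 ± 0.19 (1.04 and 1.60). Precursor genes had a median of 0.43, with 0 of 11 passing over all genes and 7 adjusted over the list alone, such as Gpr17 at 0.71 ± 0.13. The single calls of Mobp and Enpp6 ended with cyclic loess and with the mean of a gene's probes. Camera's adjusted p was 4.2e-18 and 7.8e-08 for these lists, each with adjusted p = 0.732 with an estimated correlation. Erythroid and blood genes had a median of 1.70, or 1.31 with dim signals at the floor, with 1 of 13 passing over all genes and 10 adjusted over the list alone (adjusted p = 1.3e-11, and adjusted p = 0.732 with an estimated correlation, which was 0.69). Neutrophil and monocyte genes had a median of 0.94 (0.80 at the floor), with 0 of 23 passing and 11 adjusted over the list alone, and S100a9 was at 2.51 ± 0.64. Their adjusted p was 3.6e-05, as against 6.2e-06 for reactive astrocytes (median 0.30; 5 of 25 adjusted over the list alone), 0.00011 for complement (0.26; 4 of 16), 0.00013 for ependyma (0.45; 5 of 11), 0.0045 for cytokines (0.19; 2 of 33) and 0.016 for activated microglia (0.16; 3 up and 1 down of 24), all with adjusted p = 0.732 with an estimated correlation.

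Connective-tissue and vascular lists were also ranked higher. Pericyte, fibroblast and smooth muscle genes had a median of 0.28, with 0 of 17 passing and 2 adjusted over the list alone, Col3a1 being at 1.38 ± 0.25 (list adjusted p = 0.00014). Chemokines had a median of 0.39, with Ccl5 up by 1.12 ± 0.18 and 5 up and 1 down adjusted over the list alone (adjusted p = 0.0041), activated endothelium 0.20 with 3 up alone (0.0051), and cell cycle genes 0.22 with 2 up alone (0.012). These 4 had adjusted p = 0.759 with an estimated correlation, and lymphocyte genes, with a median of 0.28 and 2 up adjusted over the list alone, had an adjusted p of 0.012 and adjusted p = 0.769 with an estimated correlation. Immediate early genes (median −0.11; 1 up and 2 down adjusted over the list alone; adjusted p = 0.012) and clock genes (−0.07; 0 alone; 0.033) were ranked lower, with adjusted p = 0.732 with an estimated correlation. Type I interferon-stimulated genes (median 0.11; adjusted p = 0.386), interferon-gamma-inducible genes (0.03; 0.893) and kynurenine genes (0.07; 0.891) were not called. Neither were homeostatic microglia (0.02; 0.744), homeostatic astrocytes (0.08; 0.0741), brain endothelium (0.06; 0.763), pan-neuronal genes (−0.05; 0.0741) or choroid plexus (0.16; 0.0741). Regional lists had medians of 0.39 (pituitary, adjusted p = 0.0671), 0.06 (hypothalamic peptides, 0.329), 0.14 (striatum, 0.230), 0.07 (cerebellum and hindbrain, 0.329) and −0.03 (olfactory bulb, cortex and hippocampus, 0.0741). Stress lists had medians of 0.03 for glucocorticoid-responsive genes (0.986), 0.06 for metallothioneins (0.986), −0.01 for heat shock (0.164), 0.01 for hypoxia (0.893) and 0.04 for prostaglandins (0.744).

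With PBS alone, blood and neutrophil genes were among the genes furthest above wild-type in Nav1.8Cre-ROSA26DTA, where Gdpd3 was at least 44.9-fold higher. S100a9 was higher by 4.39, S100a8 by 4.29, Hbb-b2 by 3.77, the haem synthesis gene Alas2 by 3.13 and Hba-a1 by 2.86, and the erythroid and blood list had a median of 1.82, with 8 of 13 genes at least 2-fold higher. Fibroblast collagens were higher too, Col3a1 by 1.97 and Col1a1 by 1.59, in a list with a median of 0.80. Interferon-stimulated genes had a median of 0.49, with Ifi27l2a at 1.71 and Rsad2 at 1.51, chemokines 0.68 with Ccl2 at 2.59, choroid plexus genes 0.48 and lymphocyte genes 0.58. Among lower genes, Hmox1 was at −1.79 and the macrophage gene Cd5l at −1.65. Across 16623 genes, 201 were at least 2-fold higher and 69 lower, whereas of 11625 measured probes with no gene name 75 were higher and 270 lower. Of 36 lists 17 stood apart as higher and 2 as lower, the latter being nociceptor genes (−0.20) and strain and transgene-locus genes (−0.22). Normexp background correction left 52 and 21 genes and turned the medians of both these lower lists positive. With the mean of a gene's probes, 0 lists stood apart as lower. With LPS, 137 genes were higher and 61 lower of 16516, and 80 and 79 of 11498 probes with no gene name. Marco was higher by 3.34 and Sv2c by 3.11, Prap1 was lower at −2.55, and the guanylate-binding gene Gbp2b was at least 48.8-fold higher. Oligodendrocyte genes had a median of 0.90 with LPS against 0.40 with PBS, with Mobp at 1.67, Opalin at 1.61 and Enpp6 at 1.60. Erythroid and blood genes had a median of 0.61, the fibroblast list −0.04, chemokines 0.10, lymphocyte genes 0.00396, choroid plexus genes −0.12 and interferon-stimulated genes −0.18, the last standing apart as lower. In the LPS pair 6 lists were apart as higher and 3 as lower of 37, and normexp background correction left 42 and 9 genes.

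**Figure D3:**
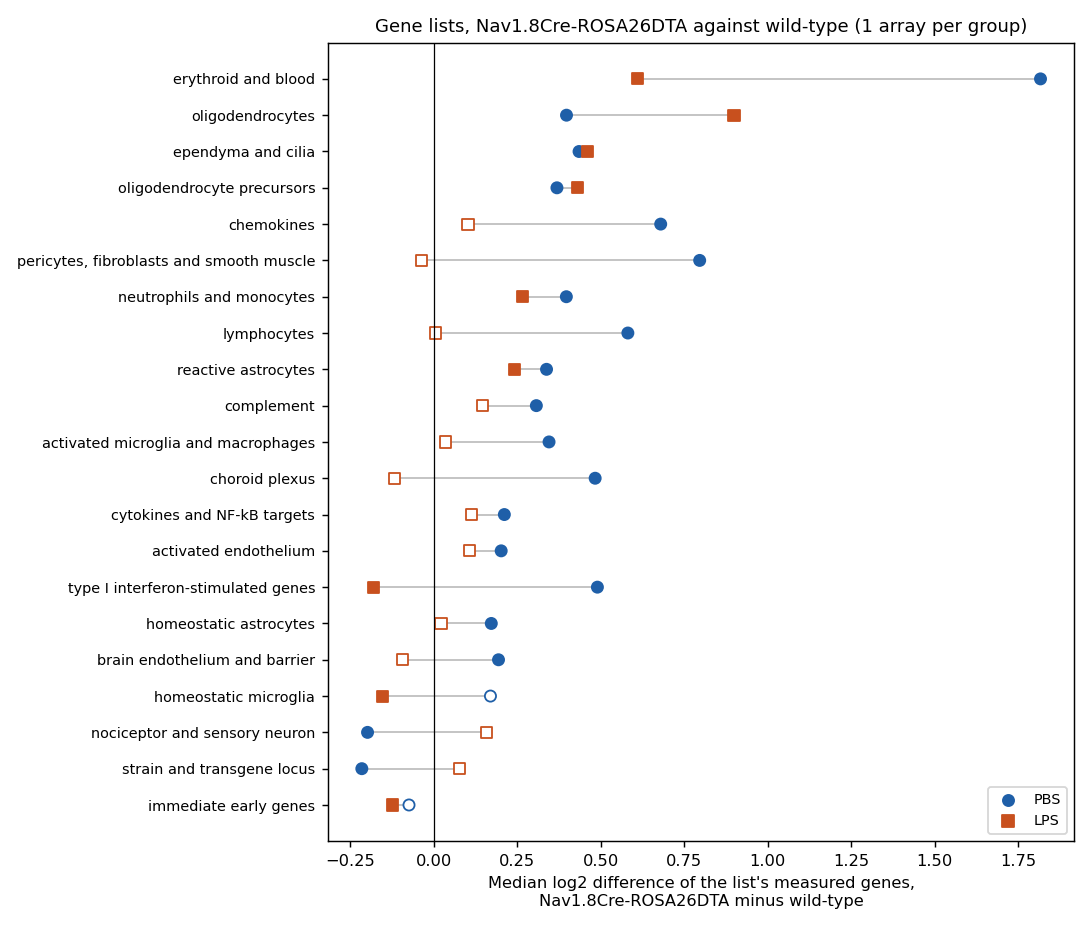
Median log2 difference of each gene list, Nav1.8Cre-ROSA26DTA minus wild-type, with PBS (circles) and with LPS (squares), 1 array per group, for lists that stood apart from random lists under either injection, with filled symbols marking where they did. Oligodendrocyte genes lie at 0.40 with PBS and 0.90 with LPS, and erythroid and blood genes at 1.82 and 0.61.

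A small set of genes differed between genotypes the same way under both injections. Among genes measured on all 4 arrays, 28 were at least 2-fold higher in Nav1.8Cre-ROSA26DTA under both, from 176 with PBS and 104 with LPS, against 1.13 for independent lists. These included Sv2c, Stbd1, Tle1, Hp, Cbln1 and Enpp6. At least 2-fold lower under both was 1 gene, from 67 and 51, against 0.21 for independent lists. Another 4 genes were at least 2-fold apart in opposite directions under the injections. The figures for independent lists take no account of genes that vary more than others. The differences correlated across genes with a Pearson coefficient of 0.23 and a Spearman coefficient of 0.18, where genes are not independent replicates. Gdpd3, a lysophospholipase D gene, was not well above background on either wild-type array and was at least 30.7-fold higher in Nav1.8Cre-ROSA26DTA. Its adjusted p of 8e-05 rests on the measured dim signals and does not test that bound. None of the 29 shared genes lay among the 200 genes on either side of Scn10a, where 0.388 would fall by count. The same held for Gt(ROSA)26Sor, where 0.552 would. Since so few would fall there by count, finding none says little about genes linked to either locus, and other loci were not examined.

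**Figure D4:**
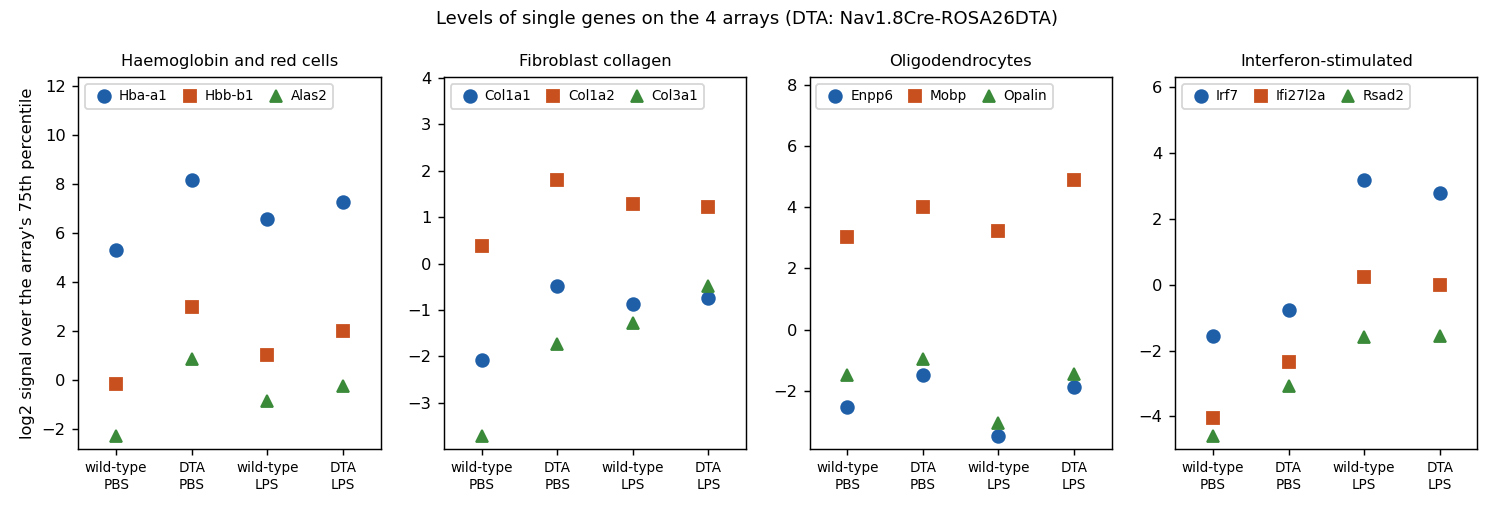
Log2 signal relative to each array's 75th percentile of 3 genes each for red cells, fibroblast collagen, oligodendrocytes and interferon-stimulated genes on the 4 arrays, 1 point per array and gene. Red cell and collagen genes are higher on the Nav1.8Cre-ROSA26DTA PBS array than on the wild-type PBS array, by 2.86 for Hba-a1 and 1.97 for Col3a1.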

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

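All tests of explanations in this part were chosen after the results were seen. The differences below were not tested, since each group held 1 array. A spread given with a median or gap is its standard error over the genes of a list, taken as independent, and not one between animals. For a value relative to random lists it is the SD of the random medians.

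Genes and lists with opposite LPS responses in the genotypes drew attention first. Alas2 was at 1.43 with LPS against PBS in wild-type and at −1.11 in Nav1.8Cre-ROSA26DTA, a difference of −2.53 (log2). The haemoglobin genes Hbb-b1 (1.21 and −1.02, a difference of −2.23) and Hbb-bt (1.09 and −1.15, a difference of −2.24) did the same, as did the cardiac myosin gene Myh6 (1.09 and −1.04, a difference of −2.13), which was chosen after its values were seen. The erythroid and blood list went from 1.12 to −0.94 (−2.05) and the pericyte, fibroblast and smooth muscle list from 0.33 to −0.57 (−0.90). The macrophage gene Cd5l went the other way, from −1.41 to 1.06 (2.48). Genotype differences opposite under the injections were found for Afp (−1.03 with PBS and 1.88 with LPS, a difference of 2.91), the lens gene Bfsp2 (1.36 and −1.63, −2.99), the chemokine gene Ccl12 (1.16 and −1.48, −2.64), 1 gene named only as a clone (2.11) and the type I interferon-stimulated list (0.49 and −0.18, −0.67). Outside the named genes, 76 of 11031 measured probes with no gene name were at least 2-fold higher with LPS in both genotypes, against 4 lower. Probes of that kind went the other way from named genes for genotype with PBS (75 higher and 270 lower of 11625) and in the difference of the responses (546 higher and 118 lower).

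The first pattern weighed was the higher level of blood, neutrophil and connective-tissue genes on the Nav1.8Cre-ROSA26DTA PBS array. Residual blood stays open for the red cell and platelet part, where the 4 platelet genes, with a median of 0.93 (spread 0.22), belong to the same list and so add no separate support. For the connective-tissue part, 8 fibroblast genes, which blood cells lack, had a median of 1.37 (spread 0.19), which blood alone would not give. They belong to the list that raised the pattern, so they too add no separate support. Those fibroblast genes exceeded 9 pericyte and smooth muscle genes by 1.02 (spread 0.24). More of the membranes around the brain would give such a gap, but both sets come from that same list. In the LPS pair the fibroblast genes had a median of −0.0436 (spread 0.20 over genes), but genotype stays open, since it cannot be told apart from the animals, and the neutrophil part was not tested.

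The second pattern was the higher level of oligodendrocyte genes on both Nav1.8Cre-ROSA26DTA arrays. More cerebellum or hindbrain tissue is argued against in the LPS pair, as far as a spread over genes can tell. The list for those regions had a median of 0.0427 there, against 0.90 for oligodendrocyte genes (a gap of 0.86, spread 0.26). Where genes of a list vary together, that spread is too small. In the PBS pair the explanation stays open, with 0.14 against 0.40 (a gap of 0.26, spread 0.26), and the regional list's member Cbln1 was higher in both pairs. For scaling that depends on intensity, the list's median over that of random lists was at least 0.35 (spread 0.05) with quantile, cyclic loess or normexp. These settings moved single genes by only 0.00877 to 0.0582 (robust SD), and a constant factor moves the list and random lists alike. They could therefore hardly have removed a difference of that size. The result does not hinge on the choice among them, but they do not decide whether scaling played a part. Genotype and the individual animals cannot be told apart with 1 array per group, although the smaller of the medians in the pairs was 0.40, and more white matter from regions outside these lists could not be tested.

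The third pattern was the smaller LPS response of type I interferon-stimulated genes in Nav1.8Cre-ROSA26DTA. Of the mean difference, 69.0% came from the PBS side, where levels were higher in Nav1.8Cre-ROSA26DTA. Whether that higher level was the whole cause stays open: the median in the LPS pair was −0.18 (spread 0.05 over genes), below the 1st percentile of random lists, but the spread between animals was not measured. For compressed signals on the Nav1.8Cre-ROSA26DTA LPS array, the difference of the responses stayed at −0.71 or lower (spread 0.07) relative to random lists with quantile or cyclic loess normalization. These moved single genes by only 0.0329 and 0.0391 (robust SD), so they could hardly have removed that difference and do not decide the question. Genotype may contribute, with a mean of −0.21 for the list in the LPS pair, but it cannot be told apart from a difference between animals in the course of the response.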

How the results depend on the processing

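The fit for genotype with an array left out was chosen after the results were seen. Most values of genes and lists kept their direction and their side of the threshold: 724 of 802 values of single genes in the averaged effects under other settings (56 no longer passed, 17 newly passed, 5 reversed), 190 of 240 with an array left out (48 no longer passed), 785 of 923 values of gene lists (76, 23 and 39), and 122 of 148 with an array left out. In single comparisons 752 of 817 gene values and 1416 of 1644 list medians moved by less than the spread they were set against. That spread is not one between animals. Of the counts, 181 of 226 stayed within 1.5 times the reported one. Some settings in these tallies could not move a gene's value. Setting dim signals to the floor leaves measured genes unchanged, as does keeping only genes above background on all arrays. Median scaling and the deposited table shift all genes of a comparison alike. The tallies for single comparisons therefore overstate stability. Counts for the averaged effects were less stable, with 56 of 92 within 1.5 times under other settings and 6 of 24 with an array left out. Signal over background limits dim genes most: normexp shrank folds, and without the filter on dim probes counts grew. Fits with an array left out hold fewer samples and 1 term, so for LPS the genotype and for genotype the LPS effect counts as error, and the latter fit was run for counts of genes only. No paired analysis was possible because each group holds 1 array, so a block would take the place of the genotype or agent term. For the other changes below the cause was not tested.

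For LPS averaged over genotypes (963 up, 777 down), the counts were 1583 and 1567 without the filter, 382 and 49 without the trend, 597 and 278 without the genotype term, and 370 to 514 up and 70 to 187 down with an array left out (fewest up without Nav1.8Cre-ROSA26DTA LPS, fewest down without Nav1.8Cre-ROSA26DTA PBS). Genes down numbered 433 with cyclic loess, 433 with the deposited table and 1290 with median scaling. For genotype (52 up, 18 down) the counts were 258 and 123 with normexp, 97 and 28 with quantile, 15 and 4 with cyclic loess, 165 and 31 with median scaling, 654 and 304 without the filter, 23 and 5 with the mean of probes, 20 and 8 with the deposited table, and 0 and 0 in limma without the trend (1035 and 441 at an unadjusted p under 0.05) or with any array left out (177 to 566 and 62 to 344).

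At 1.5-fold, the genes higher and lower were 1078 and 527 for LPS in wild-type, 1163 and 1038 for LPS in Nav1.8Cre-ROSA26DTA, 814 and 350 for genotype with PBS, 512 and 273 for genotype with LPS, and 652 and 869 for the difference of responses. With normexp at 2-fold they were 316 and 26, 267 and 83, 52 and 21, 42 and 9, and 45 and 71 in the same order, and without the filter 1311 and 655, 1310 and 806, 958 and 520, 871 and 537, and 1093 and 1291. Genes shared by the LPS responses (373 higher, 43 lower) numbered 220 and 15 with normexp and 603 and 153 without the filter. Genes shared by the genotype differences (28 higher, 1 lower) numbered 11 higher with normexp, and 183 and 42 without the filter.

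With an estimated correlation and with fry, 0 lists were called in either direction for either effect. The lowest adjusted p was 0.651 and 0.111 for LPS, and 0.732 and 0.387 for genotype, in that order. Both settings rest on 1 residual degree of freedom here and say little about stability. That limit holds for the calls with the preset correlation too, which come from the same fit and take the correlation as given. Their adjusted p is too low where members of a list vary together more than the preset. The list calls therefore hold only under the preset correlation. Lists called lower for LPS (4) ranged from 2 without the Nav1.8Cre-ROSA26DTA PBS array to 7 without the wild-type PBS array. Lists called lower for genotype (2) numbered 4 with quantile, 4 with cyclic loess and 1 without the trend. Lists apart as lower with PBS (2) numbered 1 with quantile, cyclic loess or no filter and 0 with the mean of probes. Those apart as lower with LPS (3) numbered 5 with normexp, quantile or the mean of probes, and lists apart as higher in the difference of responses (1) numbered 2 with normexp.

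Reversed list directions were mostly of lists not called, here with camera's adjusted p unless fry is named. For LPS the pericyte, fibroblast and smooth muscle list turned with quantile (0.978), cyclic loess (0.896), the mean of probes (0.935), the deposited table (0.863), and without wild-type PBS (0.0113) or wild-type LPS (0.871), with 0.932 as the highest value for any array left out. Lymphocytes turned with cyclic loess (0.920), the mean of probes (0.935), the deposited table (0.999) and without wild-type PBS (0.447; 0.142 to 0.932 over the arrays left out). Erythroid and blood genes turned without Nav1.8Cre-ROSA26DTA PBS (0.00161) or wild-type LPS (0.911), against 2.8e-06 (lower) without wild-type PBS. Oligodendrocytes turned without wild-type LPS (0.419), against 1.2e-12 (lower) without Nav1.8Cre-ROSA26DTA LPS. Prostaglandin genes turned with the mean of probes (0.935) and without Nav1.8Cre-ROSA26DTA PBS (0.907; 0.480 without wild-type PBS), pituitary genes with median scaling (0.991), no filter (0.798) and without Nav1.8Cre-ROSA26DTA PBS (0.153) or wild-type LPS (0.911; 0.0705 without wild-type PBS), and hypothalamic peptides with fry (0.941). The olfactory bulb, cortex and hippocampus list turned without wild-type PBS (0.953) or Nav1.8Cre-ROSA26DTA LPS (0.870; 0.455 without Nav1.8Cre-ROSA26DTA PBS), nociceptor genes with the mean of probes (0.951) and sex-linked genes without Nav1.8Cre-ROSA26DTA LPS (0.925; 0.542 without wild-type LPS).

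For genotype, interferon-gamma-inducible genes turned with quantile (0.983) and no filter (0.811), kynurenine genes with fry (0.476), the deposited table (0.965) and no trend (0.901), and homeostatic microglia with fry (0.964). Glucocorticoid-responsive genes turned with quantile (0.941), cyclic loess (0.929), median scaling (0.957), no filter (0.686), the deposited table (0.965) and no trend (0.901). Metallothioneins turned with normexp (0.723), quantile (0.879), cyclic loess (0.842), median scaling (0.957), no filter (0.318), the floor (0.999), the mean of probes (0.958) and the deposited table (0.965). Hypoxia genes turned with quantile (0.748), cyclic loess (0.942) and no trend (0.951), and nociceptor genes with fry (0.829), no filter (0.889), the mean of probes (0.885) and no trend (0.901). Among single comparisons, the median of nociceptor genes turned without the filter from −0.25 to 0.0807 for LPS in wild-type and from −0.20 to 0.0777 for genotype with PBS, where normexp gave 0.0330, and the strain and transgene-locus list turned from −0.22 to 0.10 with normexp for genotype with PBS. Of the genes, Extl3 in the LPS effect turned to 0.00808 with normexp, 0.0781 with quantile, 0.0882 with cyclic loess and 0.0617 with the deposited table, and lay between −0.0911 and 0.0752 with an array left out, positive without wild-type PBS or wild-type LPS. Kmo turned to −0.0288 with normexp.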

Other observations

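No test was run on the values in this part, which were picked for description after they were seen. On the 4 arrays the mean level of 10 genes of the list of red cell and platelet genes, each relative to its own mean, was −1.03 for wild-type PBS, 1.11 for Nav1.8Cre-ROSA26DTA PBS, −0.32 for wild-type LPS and 0.24 for Nav1.8Cre-ROSA26DTA LPS, and 10 of 10 were highest on the Nav1.8Cre-ROSA26DTA PBS array. Hba-a1 was lowest on the wild-type PBS array. The pericyte, fibroblast and smooth muscle list stood at −0.43, 0.39, 0.02 and 0.02 in the same order, with 12 of 17 genes highest on the Nav1.8Cre-ROSA26DTA PBS array, so the wild-type and Nav1.8Cre-ROSA26DTA PBS arrays lay on either side of both LPS arrays. Neutrophil genes stood at −1.16, −0.04, 0.50 and 0.70, and oligodendrocyte genes at −0.02, 0.34, −0.60 and 0.28. Interferon-stimulated genes stood at −1.43 on the wild-type and −0.97 on the Nav1.8Cre-ROSA26DTA PBS array.

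Genes measured on only 1 array of a pair add to the picture of the LPS pair. Besides Gbp2b, the growth factor gene Gdf2 was at least 11.3-fold higher in Nav1.8Cre-ROSA26DTA with LPS and the chitinase-like gene Chil6 at least 12.4-fold lower. With PBS the prolactin gene Prl was at least 16.5-fold higher in Nav1.8Cre-ROSA26DTA and the acetylcholine receptor gene Chrnb1 at least 15.6-fold higher, and Chrnb1 was then at least 12.2-fold lower with LPS in that genotype. Genes of the Saa family went different ways in Nav1.8Cre-ROSA26DTA, where Saa1 was 5.67 and Saa2 5.07 higher with LPS while Saa4 was lower at −3.16. The wild-type values of these genes are not reported here. The cell cycle list had a median of 0.28 in the wild-type response, above the 99th percentile of random lists, with Ccnb1 at −2.63 as the 1 member of 16 at least 2-fold lower. In the Nav1.8Cre-ROSA26DTA response its median was 0.0254, with 0 of 18 members at least 2-fold apart, while the centriole gene Stil, which is not in the list, was at −2.83. All of these are values of single arrays with no replicate check.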
